A study of Mus musculus with 12 samples.

How the data were processed

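RNA was measured by sequencing in 12 libraries of mouse gastric organoids, which are small epithelial structures grown from stomach in a gel. Per the labels, organoids were put on matrigel at first passage in medium free of growth factors and antibiotics and were kept for 4 h with bacteria. The 4 groups of 3 libraries are Fusobacterium nucleatum, Helicobacter pylori, Neisseria subflava and untreated organoids. Per the labels, total RNA was extracted with a column kit, and the column headers mark the reads as paired.

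The counts per gene were deposited by the authors as whole numbers with no normalization, per the file headers and the values themselves. The TPM values (transcripts scaled for gene length to the same sum in each library) were also deposited by the authors, per the file headers. The genome build is GRCm38, per the submitters' processing notes, while the aligner, the counting method and the use of strand are not stated. Another 24 deposited columns with RPKM and CPM values were not used here. The table lists 25759 genes. Of their identifiers, 25723 were found in the GENCODE M21 annotation, with the same start and end for 24048 and the same name for 24990. Coordinates are those of the deposited table.

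Total counts ranged from 16955155 to 23236260 per library. The edgeR package (version 4.0.16, in R 4.3.3) was run on the deposited counts with its default filter on low counts, TMM scaling and robust quasi-likelihood fits. The filter left 12805 genes, which hold 99.96% of all counts. All 12 libraries entered a single model with a coefficient per group and no replicate block. P values were adjusted over all tested genes by Benjamini-Hochberg, with a threshold of 0.05 and no fold minimum, and tests were two-sided. The plan, the rule for naming genes and 47 gene lists were fixed before the data were examined. The plan named limma on log2(TPM + 1) as the first choice and this count test in case the table held counts, which it does. Changes are given as log2 fold changes ± standard error, where the error is the size of the change divided by the square root of the quasi-likelihood F value. Expression is given as mean TPM ± SD (n = 3). The P values measure only the spread between these libraries, and the common coefficient of biological variation was 5.71%. The chi-square per degree of freedom between replicates was 2.26 to 11 for genes, so replicates differed by more than counting noise.

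The 3 comparisons with untreated organoids, the 3 comparisons between bacteria and a test of any difference among the 4 groups were made. The rule for naming genes takes the 12 largest rises and 12 largest falls in each comparison with untreated organoids, and 6 of each in the comparisons between bacteria. These genes had to pass the threshold, reach a mean of 5 TPM in the higher group and have every library of a group above every library of the other. In each gene list, up to 4 members past the threshold with the smallest adjusted p are named, or the 3 most abundant if none passed. Not every gene that meets the rule is named, and genes named outside it are said to be.

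Of the 47 fixed gene lists, 45 had at least 5 tested members. The lists of long nuclear-retained RNAs and of erythroid genes had fewer and were not tested. Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the 45 lists. The same test with a correlation estimated from the data and the rotation test fry were run as alternatives. Another 5 lists were made after the data had been seen: pancreatic acinar genes, pancreatic islet genes, genes raised by inhibitors of histone deacetylases, neuronal genes, and mitochondrial aminoacyl-tRNA synthetases other than Lars2.

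The test was tried on counts simulated from the untreated means and the sizes of all 12 libraries, with genes changed by a set fold in the Fusobacterium group (12422 genes, 50 changed genes per fold size). Only 200 genes were changed there, against 65.3% of genes called in the real comparison, so scaling under wide change was not tested. It called 58% of genes changed 1.25-fold, 80% at 1.5-fold, 88% at 2-fold and 94% at 4-fold, all in the right direction, with 12 calls among unchanged genes. In the same simulation none of 40 random lists was called and a raised list was called.

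The analysis was also run with limma on TPM with other pseudocounts, other filters on low values, median-of-ratios scaling, quantile normalization, DESeq2 (1.42.0), with only the libraries compared, with the replicate number as a block, and without each library in turn. Settings chosen after seeing the data were no scaling beyond the library total and only libraries whose column names carry the mark L1. Limma on log2(TPM + 1), which the plan named as the main test for a table without counts, was added as an alternative at that stage too. Overlaps between bacteria share their untreated libraries. Unchanged groups were therefore simulated 20 times from the mean of those libraries, with the untreated group also drawn anew and shared by the comparisons. Sequences of near-identical gene copies, such as the Sprr2 genes, Ins1 and Ins2, and genes with many pseudogenes such as those of ribosomal proteins, can share reads, and their values are uncertain to that extent.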

Results

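Transcripts were counted in 12 libraries of mouse gastric organoids kept for 4 h with Fusobacterium nucleatum, Helicobacter pylori or Neisseria subflava, or left untreated, with 3 libraries in each group. The comparisons ask how gastric epithelium responds to each bacterium and where the responses differ. The Fusobacterium libraries held 18192411, 18053330 and 16955155 counts and the Helicobacter libraries 23236260, 20616026 and 19078862. The Neisseria libraries held 22204586, 19356724 and 19202660 counts and the untreated libraries 22720399, 17248185 and 19681895. Mitochondrially encoded genes took 4.5% to 5.18% of the counts in each library.

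Each group lay apart from the others, and the Fusobacterium libraries lay farthest away. The first principal component carried 48.5% of the variance, with Fusobacterium libraries at -62.5 to -60.7 and the other 9 libraries at 10.6 to 30.2. The second carried 25.4% and placed the untreated libraries at 30.2 to 31.9, Helicobacter at -3.39 to 8.2 and Neisseria at -42.5 to -40.2. In the test among the 4 groups, 10352 of 12805 genes (80.8%) differed. Genes higher with each of the 3 bacteria than in untreated organoids numbered 650, and 524 were lower with each. Of these, 72 were higher and 25 lower by at least 2-fold with each bacterium.

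**Figure D1:**
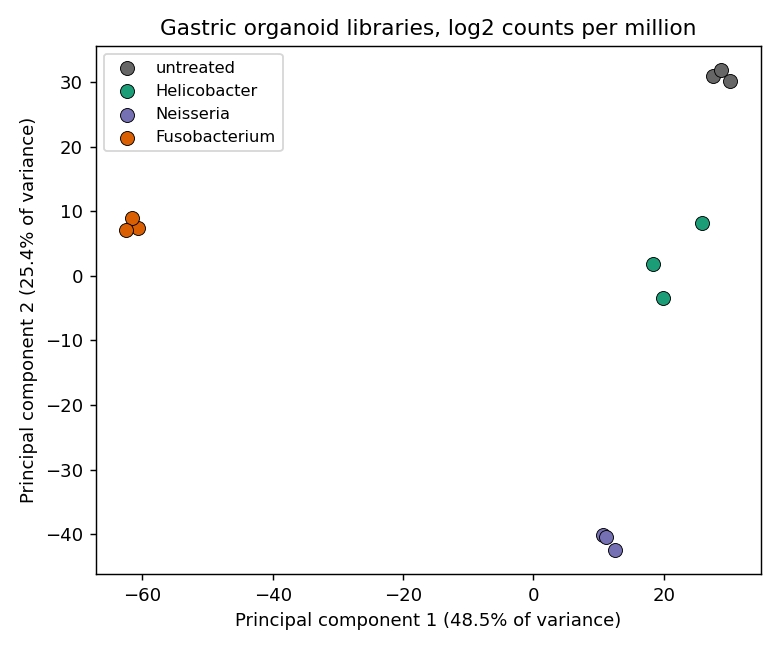
Principal components 1 (48.5% of variance) and 2 (25.4%) of log2 CPM for the 12 libraries, with a point per library coloured by group. The 3 Fusobacterium libraries sit between -62.5 and -60.7 on the first axis.

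Transcripts of endocrine and exocrine pancreas were present in the 3 untreated libraries and in Helicobacter replicate 1 and were scarce in the other 8 libraries. The gene Ins2, which encodes insulin, had 1983, 1982 and 1736 counts in the untreated libraries and 1403 in Helicobacter replicate 1. It had 30 counts in Helicobacter replicate 2 and at most 5 in each of the other 7 libraries. Over 34 pancreatic acinar and islet genes, a list made after the values were seen, the untreated libraries held 4793, 4646 and 4238 counts and Helicobacter replicate 1 held 3428. The other libraries held 350 to 693 counts over these genes. Of the 17 acinar genes, 14 were tested and 1 is in another list, and 14 fell with Fusobacterium, 4 with Helicobacter and 12 with Neisseria. Of the 17 islet genes, 14 were tested and 6 are in other lists, and 12 fell and 1 rose with Fusobacterium, 5 fell with Helicobacter, and 12 fell and 1 rose with Neisseria. Falls of Ins1, Ins2, Iapp, Ppy, Sst, Chga, Scg2, Pnlip and Ctrb1 reported for any bacterium move with these counts, and so does the list of enteroendocrine markers.

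**Figure D2:**
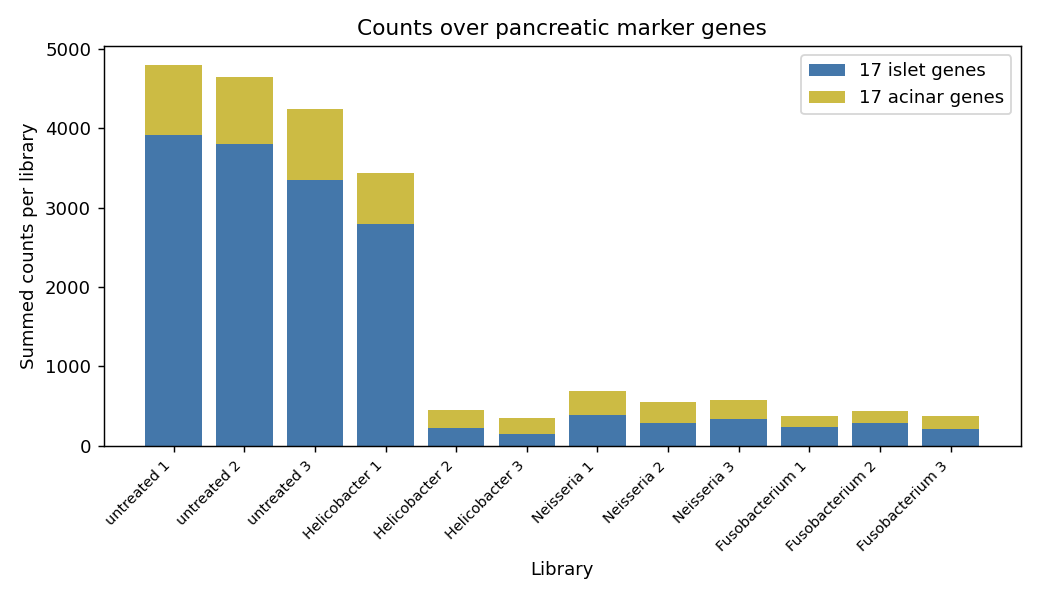
Counts of pancreatic acinar and islet genes in each of the 12 libraries. The untreated libraries and Helicobacter replicate 1 hold 3428 to 4793 counts over the 34 genes and the other 8 libraries hold 350 to 693.

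With Fusobacterium, the lists of chemokines and of aryl hydrocarbon receptor and xenobiotic genes moved up against the other genes, and those of the G2 and M phases and of ribosome biogenesis moved down. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), rose from 0.273 ± 0.12 to 158 ± 3.9 TPM. Its log2 fold change was 9.11 ± 0.11 (adjusted p = 5.86e-26, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The chemokine Cxcl2 rose by 4.84 ± 0.07 to 349 ± 14.2 TPM from 11.8 ± 1.51, and Cxcl1 by 4.05 ± 0.06. Tiparp, a further target of the aryl hydrocarbon receptor, rose by 4.17 ± 0.05. Lars2, a mitochondrial leucyl-tRNA synthetase, rose by 5.66 ± 0.26 to 989 ± 70.1 TPM from 19.2 ± 0.407. Its 3' UTR holds a stretch of 12 bases of ribosomal RNA sequence, the only length searched for. Other large rises were Syngr3 (32-fold, from 0.296 ± 0.238 to 10.4 ± 0.61 TPM), Nyap1 (4.79 ± 0.30), Mt3 (4.28 ± 0.39), Mak (4.18 ± 0.27), Rhov (4.08 ± 0.50) and Azin2 (4.06 ± 0.15), of which Azin2 was highest in untreated organoids (1.14 ± 0.0741 TPM).

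Among genes that fell with Fusobacterium, Rep15, an effector of a Rab protein of vesicle transport (chromosome 6, 147032584 to 147034245), changed by -4.90 ± 0.11 and went from 105 ± 3.1 to 3.58 ± 0.991 TPM. The signalling ligand Ihh changed by -3.65 ± 0.16 and the cytokine Clcf1 by -3.17 ± 0.11. The remaining 9 of the 12 largest falls were the pancreatic genes described for the untreated libraries, with 0 counts of Pnlip and Ppy and 1 count of Ins1 over the 3 Fusobacterium libraries. The call of Pnlip was lost whichever Fusobacterium or untreated library was left out (edgeR adjusted p from 0.0608 to 0.0868).

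Of 13 measured chemokines, 10 rose and 1 fell with Fusobacterium (camera adjusted p = 1.57e-16). Of 33 genes of the NF-kB pathway and its targets, 26 rose and 4 fell, among them Tnfaip2 (2.79 ± 0.04) and the inhibitor Nfkbia (1.70 ± 0.06), with a camera adjusted p = 2.45e-16. Cytokines and epithelial growth factors rose in 13 of 22 cases and fell in 4, with Il1a at 1.89 ± 0.05 and Ereg at 1.74 ± 0.04. Hypoxia and glycolysis genes rose in 23 of 31 cases and fell in 2, including the glucose transporter Slc2a1 (1.70 ± 0.05) and Pfkfb3 (2.29 ± 0.06). Of 15 aryl hydrocarbon receptor and xenobiotic genes, 7 rose and 3 fell, with Cyp1b1 at 1.75 ± 0.04 and Ahrr at 3.40 ± 0.14. Immediate-early genes rose in 22 of 34 cases and fell in 8, with Atf3 at 2.23 ± 0.07 and Myc at -1.61 ± 0.06. Metallothionein and metal-transport genes rose in 9 of 14 cases and fell in 3, and the iron-storage gene Fth1 rose by 1.03 ± 0.05. Prostaglandin synthesis genes rose in 7 of 13 cases and fell in 4, with Ptges at 3.01 ± 0.07 and Ptgs2 at 1.91 ± 0.04. The prostaglandin call was lost with limma on TPM (pseudocount 0.1, camera adjusted p = 0.108), with quantile normalization (camera adjusted p = 0.209) and without a filter on low counts. These 8 lists stood above the other genes with the preset and with the estimated correlation.

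NRF2 oxidative-stress genes rose in 19 of 36 cases and fell in 9 with Fusobacterium (camera adjusted p = 2.08e-08, adjusted p = 0.0748 with an estimated correlation). Heme oxygenase Hmox1 rose by 3.38 ± 0.05, Osgin1 by 3.23 ± 0.07, sulfiredoxin Srxn1 by 2.54 ± 0.04 and the glutathione-synthesis gene Gclc by 1.77 ± 0.04. Integrated stress response genes rose in 15 of 31 cases and fell in 6 (adjusted p = 0.0802 with an estimated correlation), with Chac1 at 3.67 ± 0.13. p53 targets rose in 12 of 26 cases and fell in 10 (adjusted p = 0.0802 with an estimated correlation), with Gdf15 at 2.93 ± 0.06, and the call of the p53 list was lost with limma on TPM (pseudocount 0.1, camera adjusted p = 0.348), with quantile normalization (camera adjusted p = 0.234) and without a filter on low counts. Integrins, matrix genes and proteases rose in 18 of 38 cases and fell in 9 (adjusted p = 0.224 with an estimated correlation), with the plasminogen activators Plat at 2.56 ± 0.04 and Plau at 1.83 ± 0.07. Cholesterol synthesis genes rose in 15 of 25 cases and fell in 4 (adjusted p = 0.176 with an estimated correlation).

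Of 40 genes of the G2 and M phases, 36 fell and 1 rose with Fusobacterium (camera adjusted p = 2.06e-10), with cyclin Ccna2 at -1.06 ± 0.05 and Kif23 at -0.99 ± 0.05. Ribosome biogenesis genes fell in 25 of 32 cases and rose in 3, with Gnl3 at -1.27 ± 0.06 and Dkc1 at -1.25 ± 0.06. Mucous neck cell markers fell in 10 of 11 cases, with Aqp5 at -1.06 ± 0.06. These 3 lists stood below the other genes with the preset and with the estimated correlation. S-phase genes fell in 22 of 35 cases and rose in 4 (adjusted p = 0.0737 with an estimated correlation). Genes of gastric epithelial identity fell in 15 of 21 cases and rose in 2 (adjusted p = 0.0748 with an estimated correlation), and the transcription factor genes Foxa1, Gata5 and Sox2 changed by -1.34 ± 0.05, -1.42 ± 0.06 and -1.86 ± 0.11. Mucin and mucus genes fell in 15 of 21 cases and rose in 3 (adjusted p = 0.29 with an estimated correlation). DNA repair genes fell in 33 of 62 cases and rose in 8 (adjusted p = 0.0698 with an estimated correlation). Counts adjusted over the list alone were the same for each of these 20 lists except cholesterol synthesis, where 16 rose. Over all genes, 8356 passed the threshold with Fusobacterium, of which 4206 were higher and 4150 lower, and 1268 were higher and 615 lower by at least 2-fold.

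With Helicobacter, the changes were fewer, and hypoxia, aryl hydrocarbon receptor and amino-acid stress genes led them. Cyp1a1 rose by 7.36 ± 0.12 to 43.1 ± 3.36 TPM from 0.273 ± 0.12 (adjusted p = 7.48e-23, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ahrr, the repressor of the aryl hydrocarbon receptor, rose by 3.86 ± 0.13 to 11.2 ± 0.587 TPM. Chac1, which degrades glutathione, rose by 3.83 ± 0.12 to 49.8 ± 2.3 TPM from 3.78 ± 1.45, and Trib3 by 3.03 ± 0.09. Bnip3, a hypoxia-induced gene of mitophagy, rose 8.02-fold to 173 ± 5.53 TPM from 23.1 ± 1.05. Other large rises were Ankrd37 (3.05 ± 0.10), the prostaglandin synthase Ptges (2.72 ± 0.07), the lactate transporter Slc16a3 (2.72 ± 0.06), Tiparp (2.63 ± 0.05), Ndrg1 (2.48 ± 0.04) and Cyp1b1 (2.46 ± 0.04).

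Among the 12 largest falls with Helicobacter, the gastrokine genes Gkn1 and Gkn2 changed by -1.23 ± 0.18 and -1.17 ± 0.19, and Gkn1 went from 558 ± 119 to 222 ± 44.3 TPM. The gland mucin Muc6 changed by -1.35 ± 0.17, pepsinogen C (Pgc) by -1.42 ± 0.17, and the antimicrobial lectins Reg3b and Reg3g by -2.15 ± 0.47 and -1.40 ± 0.18. The transcription factor gene Sox9 changed by -1.18 ± 0.09 and the immediate-early gene Fosb by -2.30 ± 0.15. Akr1c14 (-1.56 ± 0.16), Lypd8 (-1.55 ± 0.30), Igfbp5 (-1.22 ± 0.15) and the islet gene Ppy (-2.39 ± 0.74) complete the 12, and the fall of Ppy moves with the pancreatic counts of the libraries. Its call was lost without any 1 of the untreated libraries and without Helicobacter replicate 2 or 3 (edgeR adjusted p from 0.0647 to 0.137).

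Of 31 hypoxia and glycolysis genes, 30 rose and none fell with Helicobacter (camera adjusted p = 2.55e-279), and the oxygen-sensing gene Egln3 rose by 2.02 ± 0.05. Integrated stress response genes rose in 26 of 31 cases and fell in 2 (camera adjusted p = 1.12e-45), with Atf3 at 1.56 ± 0.08 and Vldlr at 1.58 ± 0.07. Of 15 aryl hydrocarbon receptor and xenobiotic genes, 8 rose and 1 fell. NF-kB genes rose in 13 of 33 cases and fell in 1, with Tnfaip2 at 0.90 ± 0.04. Cytokines and growth factors rose in 8 of 22 cases and none fell, with Vegfa at 1.63 ± 0.06. Cholesterol synthesis genes rose in 16 of 25 cases and fell in 1, p53 targets rose in 12 of 26 and fell in 2, prostaglandin genes rose in 4 of 13 and fell in 1, and actin cytoskeleton genes rose in 22 of 59 and fell in 2. Mucous neck cell markers fell in 6 of 11 cases and rose in 1, with Tff2 at -1.12 ± 0.08 and Cftr at -0.71 ± 0.06. These 10 lists passed with the preset and with the estimated correlation, while quantile normalization lost the calls of prostaglandin genes (camera adjusted p = 0.0641) and actin genes (camera adjusted p = 0.0929), and limma with a pseudocount of 5 TPM also lost that of prostaglandin genes. Adjusted over the list alone, 17 NF-kB genes, 9 xenobiotic genes, 17 cholesterol genes and 25 actin genes rose, and 7 neck cell markers and 3 actin genes fell. For the other 5 of these lists the counts adjusted over the list alone were the same.

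Chemokines did not stand apart with Helicobacter, where 2 of 13 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.318). Mucin and mucus genes fell in 10 of 21 cases and rose in 1 (adjusted p = 0.0671 with an estimated correlation), and 13 fell adjusted over the list alone. Unfolded protein response genes rose in 11 of 28 cases and fell in 1 (adjusted p = 0.127 with an estimated correlation), and 16 rose adjusted over the list alone. Ribosome biogenesis genes fell in 11 of 32 cases and rose in 1 (adjusted p = 0.0704 with an estimated correlation), and 15 fell and 2 rose adjusted over the list alone. Genes of cytosolic ribosomal proteins rose in 23 of 46 cases (adjusted p = 0.663 with an estimated correlation), and 30 rose adjusted over the list alone. Integrins, matrix genes and proteases rose in 9 of 38 cases and fell in 5 (adjusted p = 0.26 with an estimated correlation), and 6 fell adjusted over the list alone. Squamous markers rose in 5 of 19 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.239 with an estimated correlation). Their median change was 0.0406 and their mean -0.0191. Nuclear-encoded oxidative phosphorylation genes rose in 10 of 43 cases (adjusted p = 0.828 with an estimated correlation), and 11 rose adjusted over the list alone. The squamous call was also lost without Helicobacter replicate 3 (camera adjusted p = 0.0528) and without untreated replicate 1 (camera adjusted p = 0.0526). The oxidative phosphorylation call was lost without Helicobacter replicate 1 or 3 and without untreated replicate 1 or 2, with adjusted p of 0.0655 to 0.283 in the camera test.

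Over all genes, 2419 passed the threshold with Helicobacter, of which 1349 (55.8%) were higher and 1070 lower, and 119 were higher and 49 lower by at least 2-fold. The count was 1594 without untreated replicate 1, 1596 without untreated replicate 2 and 3136 without Helicobacter replicate 2. With no scaling beyond the library total, a setting chosen after the data were seen, 863 genes were higher and 1824 lower (32.1% higher), and with limma on TPM (pseudocount 0.1) 668 were higher and 2011 lower.

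With Neisseria, the lists of hypoxia and glycolysis, of the integrated stress and unfolded protein responses and of the NF-kB pathway moved up against the other genes. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose by 8.71 ± 0.30 to 14.3 ± 0.587 TPM from 0.0414 ± 0.0718 (adjusted p = 1.4e-17, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cyp1a1 rose by 8.67 ± 0.11 to 99.2 ± 1.47 TPM. The stress genes Chac1, Trib3 and Ddit3 rose by 5.49 ± 0.12, 5.21 ± 0.08 and 4.92 ± 0.10, and Ddit3 reached 353 ± 11.4 TPM from 13.6 ± 1.8. Cxcl2 rose by 4.87 ± 0.07 to 302 ± 10.4 TPM and the epithelial cytokine gene Il17c by 5.04 ± 0.48. Derl3, of protein degradation at the endoplasmic reticulum, rose by 5.13 ± 0.42, Tiparp by 4.62 ± 0.05, and the cornified-envelope genes Sprr2d and Sprr2e, which can share reads, by 5.55 ± 0.48 and 5.39 ± 0.42. Among the 12 largest falls, Fosb changed by -3.42 ± 0.18, Rep15 by -2.98 ± 0.09 and Lipt2 by -2.53 ± 0.16. The other 9 were the pancreatic genes, with 0 counts of Pnlip and Ppy and 3 of Ins1 over the Neisseria libraries. The call of Pnlip was lost whichever Neisseria or untreated library was left out (edgeR adjusted p from 0.0786 to 0.105).

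All 31 hypoxia and glycolysis genes rose with Neisseria (camera adjusted p = 6.47e-157), with Ero1l at 4.23 ± 0.06 and Ndrg1 at 3.95 ± 0.05. Integrated stress response genes rose in 30 of 31 cases and fell in 1 (camera adjusted p = 3.87e-73). Of 28 unfolded protein response genes, 26 rose and 1 fell, among them the chaperone Hspa5 (2.25 ± 0.04) at 2401 ± 25.6 TPM against 581 ± 0.838, and Herpud1 (3.75 ± 0.06). NF-kB genes rose in 30 of 33 cases and none fell, with the apoptosis inhibitor Birc3 at 2.28 ± 0.06. Chemokines rose in 11 of 13 cases and fell in 1, with Ccl20 at 3.68 ± 0.08, and cytokines and growth factors rose in 16 of 22 and fell in 2, with Vegfa at 2.82 ± 0.06. Antimicrobial genes rose in 13 of 28 cases and fell in 4, with lipocalin Lcn2 at 1.20 ± 0.06 and Duoxa2, a maturation factor of an oxidase, at 1.72 ± 0.05. Of 15 aryl hydrocarbon receptor and xenobiotic genes, 9 rose and 2 fell, with Cyp1b1 at 2.71 ± 0.04. Cholesterol synthesis genes rose in 19 of 25 cases and fell in 1, p53 targets rose in 19 of 26 and fell in 4, and immediate-early genes rose in 18 of 34 and fell in 9. G2 and M phase genes fell in 32 of 40 cases and rose in 1, ribosome biogenesis genes fell in 21 of 32 and rose in 2, and stem cell and Wnt target genes fell in 12 of 24 and rose in 4, with Sox9 at -2.31 ± 0.10 and Lgr4 at -0.73 ± 0.05. These 14 lists passed with the preset and with the estimated correlation, while quantile normalization lost the call of immediate-early genes (camera adjusted p = 0.0558). Adjusted over the list alone, 20 cholesterol genes rose, and 3 xenobiotic, 10 immediate-early and 22 ribosome biogenesis genes fell, while the other counts of these lists were the same.

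Pattern recognition genes rose in 15 of 28 cases and fell in 4 with Neisseria, also adjusted over the list alone (adjusted p = 0.0514 with an estimated correlation), with the receptors Nod2 at 2.27 ± 0.10 and Cd14 at 0.67 ± 0.05. Prostaglandin genes rose in 5 of 13 cases and fell in 5, also adjusted over the list alone (adjusted p = 0.0506 with an estimated correlation), with Ptges at 3.82 ± 0.07 and the degrading enzyme Hpgd at -1.34 ± 0.14. Apoptosis and necroptosis genes rose in 14 of 29 cases and fell in 8 (adjusted p = 0.0677 with an estimated correlation), and 16 rose adjusted over the list alone, with Fas at 2.12 ± 0.13. Ribosomal protein genes rose in 40 of 46 cases (adjusted p = 0.666 with an estimated correlation), and 41 rose adjusted over the list alone. Integrins, matrix genes and proteases rose in 15 of 38 cases and fell in 10, also adjusted over the list alone (adjusted p = 0.378 with an estimated correlation), with Itgav at 1.78 ± 0.04 and Ctgf at -1.65 ± 0.05. Over all genes, 6511 passed the threshold with Neisseria, of which 3250 (49.9%) were higher and 3261 lower, and 573 were higher and 352 lower by at least 2-fold. With no scaling beyond the library total, 1984 genes were higher and 5402 lower (26.9% higher), the median over all genes lay at -0.185, and changes with Neisseria are therefore relative to the scaling used.

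**Figure D3:**
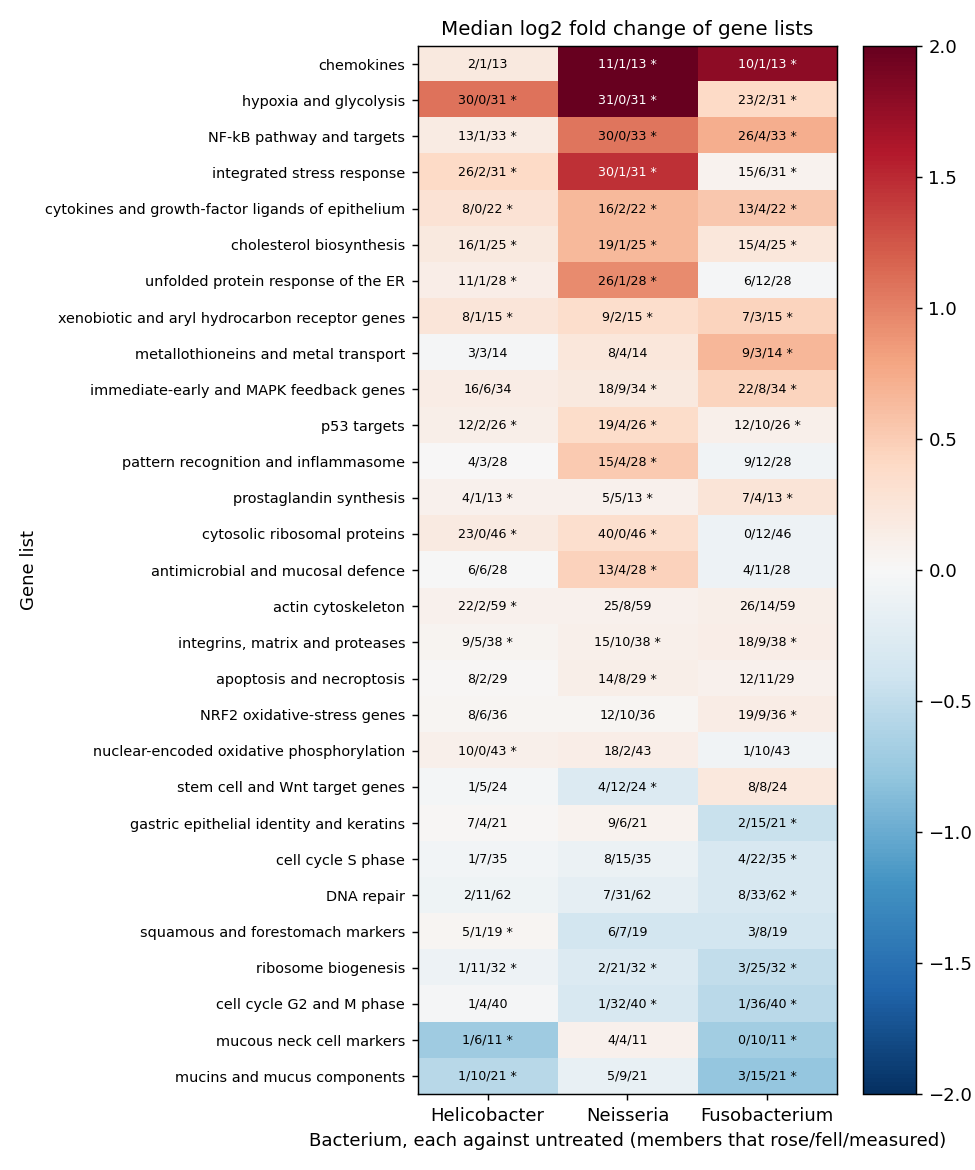
Median log2 fold change with each bacterium against untreated organoids, on a colour scale that stops at -2 and 2, with the numbers that rose and fell of those measured. Only fixed gene lists that passed for at least 1 bacterium are drawn. A star marks a camera adjusted p under 0.05, and hypoxia and glycolysis genes carry medians of 0.397 with Fusobacterium, 1.09 with Helicobacter and 1.99 with Neisseria.

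**Figure D4:**
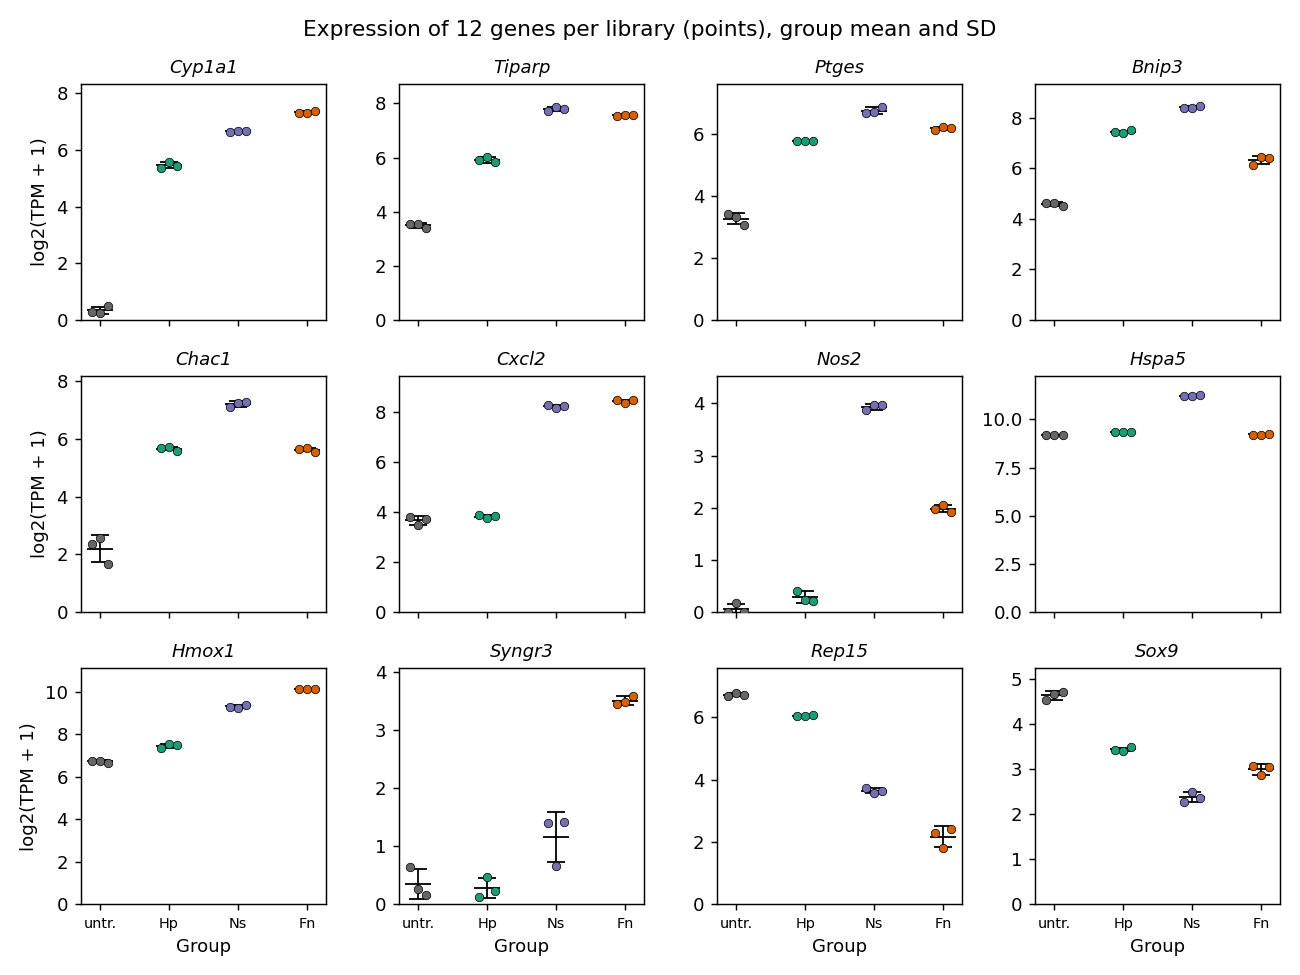
Expression of 12 genes, chosen after their values were seen, as log2(TPM + 1) in untreated organoids (untr.) and with Helicobacter (Hp), Neisseria (Ns) and Fusobacterium (Fn), with a point per library and bars for the group mean and SD (n = 3). Hspa5 has means of 581 TPM in untreated organoids, 645 with Helicobacter, 2401 with Neisseria and 595 with Fusobacterium.

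Set directly against Helicobacter, Fusobacterium moved the lists of chemokines and NF-kB genes up against the other genes and that of the G2 and M phases down. Cxcl2 was higher by 4.59 ± 0.07 (349 ± 14.2 against 13.2 ± 0.537 TPM; adjusted p = 1.54e-23, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Cxcl1 by 3.87 ± 0.06. Syngr3 (5.41 ± 0.41), Lars2 (5.40 ± 0.26), Nyap1 (5.22 ± 0.31) and Rhov (3.96 ± 0.49) were also higher. Rep15 (-4.32 ± 0.12), Ihh (-3.38 ± 0.17), Kctd14 (-3.19 ± 0.09), the vasoconstrictor gene Edn1 (-3.18 ± 0.10), Clcf1 (-2.94 ± 0.11) and Ankrd37 (-2.79 ± 0.10) were lower. Of 13 chemokines 9 were higher and 2 lower, of 33 NF-kB genes 24 were higher and 5 lower, and of 14 metallothionein and metal-transport genes 10 were higher and 3 lower. Of 40 G2 and M phase genes 35 were lower and none higher, and of 32 ribosome biogenesis genes 25 were lower and 4 higher. These 5 lists passed with both correlations, with the same counts adjusted over the list alone. NRF2 genes were higher in 19 of 36 cases and lower in 12 (adjusted p = 0.0831 with an estimated correlation), and 20 were higher adjusted over the list alone, with Srxn1 at 2.87 ± 0.04. Hypoxia genes were lower in 24 of 31 cases and higher in 5 (adjusted p = 0.0617 with an estimated correlation), and 6 were higher adjusted over the list alone. In all, 8361 genes passed, 4073 higher (48.7%) and 4288 lower. With limma on TPM (pseudocount 0.1), 4784 were higher (61.6%) and 2987 lower.

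Set against Neisseria, Fusobacterium gave far lower transcripts of the unfolded protein and integrated stress responses and of hypoxia. Hspa5 was lower by a log2 value of -2.25 ± 0.04 and Ddit3 by -3.71 ± 0.09. Of 28 unfolded protein response genes 26 were lower and 2 higher (camera adjusted p = 4.38e-44), of 31 integrated stress response genes 29 were lower and 1 higher, and of 31 hypoxia genes 29 were lower and 2 higher. Antimicrobial genes were lower in 18 of 28 cases and higher in 1, and pattern recognition genes lower in 18 of 28 and higher in 3, with Cd14 at -2.35 ± 0.05. NF-kB genes were lower in 21 of 33 cases and higher in 6. These 6 lists passed with both correlations, and the counts adjusted over the list alone were the same except for 7 higher NF-kB genes. NRF2 genes were higher in 21 of 36 cases and lower in 7, also adjusted over the list alone (adjusted p = 0.135 with an estimated correlation), with Gclc at 2.44 ± 0.04. Lars2 (4.79 ± 0.25), Mt3 (4.15 ± 0.39), Tmem121 (3.99 ± 0.34), Nyap1 (3.85 ± 0.27), Cldn9 (3.81 ± 0.39) and Dpf1 (3.77 ± 0.28) were the largest differences upward. Sprr2e (-4.67 ± 0.39), the secretory-cell transcription factor gene Bhlha15 (-4.47 ± 0.24), Adm2 (-3.93 ± 0.19), Ankrd37 (-3.92 ± 0.09), Derl3 (-3.86 ± 0.37) and the adhesion molecule gene Vcam1 (-3.74 ± 0.12) were the largest downward. In all, 8527 genes passed, 4156 higher (48.7%) and 4371 lower, while with no scaling beyond the library total 5664 were higher (65.9%) and 2933 lower, with a median of 0.17 over all genes.

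Set against Neisseria, Helicobacter moved the lists of chemokines, NF-kB genes, hypoxia and the integrated stress and unfolded protein responses down against the other genes. Nos2 was lower at -6.04 ± 0.22 (0.224 ± 0.0953 against 14.3 ± 0.587 TPM; adjusted p = 1.53e-16, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Sprr2d (-4.80 ± 0.43), Vcam1 (-4.69 ± 0.13), Cxcl2 (-4.62 ± 0.07), Sprr2e (-4.52 ± 0.38) and Ccl20 (-4.06 ± 0.08) were lower too. Rep15 (2.40 ± 0.09), Lipt2 (1.90 ± 0.16), the epithelial transcription factor gene Ovol2 (1.81 ± 0.18), Mycn (1.73 ± 0.12), Tmie (1.63 ± 0.15) and Acnat1 (1.59 ± 0.20) were higher. Chemokines were lower in 10 of 13 cases and higher in 1 (camera adjusted p = 1.69e-49), and 11 were lower adjusted over the list alone. NF-kB genes were lower in 30 of 33 cases, integrated stress response genes lower in 29 of 31 and higher in 1, and hypoxia genes lower in 31 of 31, with the same counts adjusted over the list alone. Unfolded protein response genes were lower in 25 of 28 cases, and 26 adjusted over the list alone. G2 and M phase genes were higher in 33 of 40 cases, and 35 adjusted over the list alone. Chief cell markers were lower in 6 of 8 cases, also adjusted over the list alone, with Pgc at -2.21 ± 0.17 and the transcription factor gene Xbp1 at -0.60 ± 0.04. These lists passed with both correlations. In all, 4704 genes passed, 2268 higher (48.2%) and 2436 lower, while with no scaling beyond the library total 4000 were higher (71.5%) and 1597 lower, with a median of 0.123 over all genes.

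Changes with Helicobacter and Neisseria overlapped, with 1162 genes higher and 867 lower with both and 59 in opposite directions. Independent lists of those sizes would share 342 higher and 272 lower genes. Unchanged groups simulated with common controls shared 0, an outcome set by the near absence of calls when no gene changes. That 0 does not tell how much overlap common controls add among called genes. With limma on TPM (pseudocount 0.1) Helicobacter and Neisseria shared 550 higher and 1781 lower genes. With no scaling beyond the library total they shared 695 and 1619, so the balance of rises and falls depends on the scaling. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.224 against 0.0358 in the simulation, a difference of 0.188, and Pearson r was 0.679 against 0.488. For Fusobacterium and Neisseria, 1625 genes were higher and 1688 lower with both and 1382 went in opposite directions, where independent lists would share 1068 and 1057. With limma on TPM (pseudocount 0.1) they shared 1014 higher and 2441 lower genes. Their covariance was 0.398 against 0.0355 simulated, a difference of 0.363, and r was 0.535 against 0.482. For Fusobacterium and Helicobacter, 724 genes were higher and 619 lower with both and 462 went in opposite directions, where independent lists would share 443 and 347. With limma on TPM (pseudocount 0.1) they shared 459 higher and 1003 lower genes. Their covariance was 0.173 against 0.036 simulated, a difference of 0.137, and r was 0.426 against 0.492. The simulated r is set by the common controls when no gene changes. An r above or below it therefore does not measure a shared response in any of these pairs. The 3 untreated libraries cannot be split into parts of at least 2, so part of each excess may come from the shared controls. Pancreatic genes, high in the untreated libraries, also enter these values. The 14 tested acinar genes had mean log2 fold changes of -6.05 with Fusobacterium, -1.93 with Helicobacter and -5.67 with Neisseria. Those of the 14 tested islet genes were -5.84, -1.84 and -5.87. How much of each covariance these genes carry was not computed. Cyp1a1, Tiparp, Chac1 and Ptges rose with each bacterium.

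Interferon-stimulated genes passed as a list with none of the bacteria (camera adjusted p = 0.83 with Fusobacterium, 0.986 with Helicobacter and 0.696 with Neisseria). Of 33 such genes, 10 rose and 7 fell with Fusobacterium, 1 rose and 2 fell with Helicobacter, and 9 rose and 4 fell with Neisseria. Adjusted over the list alone, 10 rose and 6 fell with Fusobacterium, 1 rose with Helicobacter, and 8 rose and 3 fell with Neisseria. Their median change was -0.0373 with a mean of 0.0918 with Fusobacterium, where camera pointed up, and 0.0429 with a mean of 0.0741 with Helicobacter, where camera pointed down. Enteroendocrine markers fell in 9 of 11 cases with Fusobacterium, 3 with Helicobacter and 8 with Neisseria, where 1 rose, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.145, 0.0574 and 0.221). These markers include islet genes such as Chgb and Pcsk2, which move with the pancreatic counts of the libraries.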

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

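The use of limma on log2(TPM + 1) as an alternative, no scaling beyond the library total and only libraries marked L1 were chosen after the data were seen. The other settings were planned. Counts of changed genes stayed within 1.5 times the main count under every setting run except for Helicobacter against untreated, which gave 1594 to 3136 with each library left out in turn, 1594 without untreated replicate 1 and 1596 without untreated replicate 2, and the cause was not tested. Only libraries marked L1 gave 1669 there, and without Helicobacter replicate 1 there were 1076 higher and 840 lower genes. With an estimated correlation, 11 lists passed for Fusobacterium, 10 for Helicobacter, 5 for Fusobacterium against Helicobacter and 6 for Fusobacterium against Neisseria. With fry, which does not compare lists with other genes, 40 passed for Fusobacterium, 26 for Helicobacter, 36 for Neisseria, 38 for Fusobacterium against Helicobacter, 40 for Fusobacterium against Neisseria and 30 for Helicobacter against Neisseria, but ribosomal proteins (0.0548) and oxidative phosphorylation (0.152) lost their calls for Helicobacter and ribosomal proteins (0.0898) for Helicobacter against Neisseria. No called list changed direction under the scalings or with a library left out. Integrins, matrix genes and proteases lost their call in each comparison with untreated organoids with a pseudocount of 0.1 TPM (0.108 for Fusobacterium, 0.149 for Helicobacter, 0.146 for Neisseria) and with quantile normalization (0.0697, 0.252 and 0.9). Prostaglandin synthesis lost its call under these settings for Fusobacterium (0.108 and 0.209) and Neisseria (0.112 and 0.288) and under quantile normalization for Helicobacter (0.0641). Against untreated organoids, calls were also lost for p53 targets (0.348 and 0.234) and the integrated stress response (0.0697, quantile) with Fusobacterium, and for actin (0.0929, quantile), squamous markers (0.0713, quantile) and oxidative phosphorylation (0.124, no scaling) with Helicobacter. With Neisseria they were lost for apoptosis (0.071, 0.0781 and, with no scaling, 0.0523) and immediate-early genes (0.0558, quantile). The other filters and pseudocounts lost calls only of lists named here. Without a filter on low counts, camera kept 18 of 20 lists for Fusobacterium (p53 targets and prostaglandin lost), 16 of 17 for Helicobacter (squamous lost) and 17 of 19 for Neisseria (integrins and prostaglandin lost), and with a pseudocount of 5 TPM it kept 17, 14 (squamous, integrins and prostaglandin lost) and 16.

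Counts of shared genes moved too. With a pseudocount of 0.1 TPM, Fusobacterium and Helicobacter shared 459 higher and 1003 lower genes, Fusobacterium and Neisseria 1014 higher, and Helicobacter and Neisseria 550 higher and 1781 lower. With a pseudocount of 1 TPM these were 448, 1057, 1009, 539 and 1852. With no scaling beyond the library total, Fusobacterium and Helicobacter shared 983 lower genes, and Helicobacter and Neisseria 695 higher and 1619 lower. With at least a 2-fold change, the numbers higher, lower and opposite were 75, 29 and 4 for Fusobacterium and Helicobacter, 284, 134 and 37 for Fusobacterium and Neisseria, and 112, 31 and 0 for Helicobacter and Neisseria, since fewer genes enter. Apart from that, the cause was not tested.

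Of 505 named values for 254 genes, 482 kept direction and call in every setting run. The others include pancreatic genes among the largest falls: Pnlip for Fusobacterium and Neisseria and Ppy for Helicobacter with libraries left out, Ins2 for Fusobacterium (0.109) and Neisseria (0.0777) and Ins1 for Neisseria (0.0544) under quantile normalization, and Sst (0.0643 for Fusobacterium, 0.0818 for Neisseria) and Ctrb1 (0.0888, Neisseria) with DESeq2. The rest are Atp5h, Cox4i1, Cox5a, Cox7b, Hpgds, Pla2g4a, Rpl37 and Rps10 for Helicobacter, and Rpl4, Rpl5 and Rpl15 in comparisons with Neisseria. Rpl7 (0.0003089) and Rpl4 (0.004026) reversed for Helicobacter against Neisseria under quantile normalization, with no call, and the cause was not tested. Named genes were picked as clear changes in the same data, which favours such stability. Over all tested calls, limma on TPM (pseudocount 0.1) kept 7487 of 7972 for Fusobacterium, 1682 of 2376 for Helicobacter and 4870 of 6336 for Neisseria. It called 0, 0 and 20 in reverse. For Fusobacterium against Neisseria it kept 6358 of 8180 and called 56 in reverse. The replicate block gave 8369, 2560 and 6535 changed genes for Fusobacterium, Helicobacter and Neisseria, 8367, 8543 and 4739 between bacteria in the order above, and 10373 among the 4 groups. Replicate numbers did not pair the libraries: 6 of 18 same-number pairs correlated over 0.1, and 5 of 12 libraries correlated best with their own number. Under the block, 4 further lists passed: enteroendocrine markers for Helicobacter (camera adjusted p = 0.0396), fatty acid (0.0442) and mitochondrially encoded genes (0.0478) for Fusobacterium against Helicobacter, and ribosome biogenesis for Fusobacterium against Neisseria (0.0495). In counts simulated from the untreated means (12422 genes), 58% of genes with the smallest simulated change were recovered.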

Other observations

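The tests on pancreatic transcripts, near-silent genes and Lars2, including those on GC content and on mitochondrial synthetases, were chosen after these results were seen. Some values of histone deacetylase targets, such as that of Plat, had been reviewed before that test was written.

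The claudin genes Cldn4 and Cldn2 changed in opposite directions with each bacterium, and the list of junction genes that holds them did not pass (camera adjusted p = 0.718 with Fusobacterium, 0.427 with Helicobacter and 0.221 with Neisseria). Cldn4, which tightens junctions, rose by 1.20 ± 0.04 with Fusobacterium, 0.53 ± 0.04 with Helicobacter and 1.15 ± 0.04 with Neisseria. Cldn2, which forms cation channels, changed by -0.98 ± 0.04, -0.25 ± 0.04 and -1.55 ± 0.04. Rhoc, a small GTPase of the actin cytoskeleton, rose by 1.24 ± 0.05, 0.47 ± 0.05 and 1.29 ± 0.05. The lipopolysaccharide co-receptor gene Cd14 changed by -1.67 ± 0.05 with Fusobacterium and 0.67 ± 0.05 with Neisseria, and lay -2.35 ± 0.05 lower with Fusobacterium in the direct comparison.

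Pancreatic transcripts were high in the 3 untreated libraries and in Helicobacter replicate 1. Loss of such cells on contact with Helicobacter stays open, since replicate 1 held 7.32 times the mean of replicates 2 and 3 in summed pancreatic CPM, and a single library does not exclude loss that is uneven between cultures. A single source of pancreatic RNA or cells remains a candidate, since the lowest correlation of the 34 genes between any 2 of the 4 libraries was 0.959, though pancreatic-type cells within these organoids would give the same, and 3 of the genes averaged over 10 counts in the other 8 libraries. Loss with Fusobacterium or Neisseria, and an order effect in the 4 lowest library numbers (a chance of 0.111 that the next number would fall to the fourth by luck), cannot be told apart from such a source, because the design gives each treatment a single set. The 6 libraries held 11.3% of the untreated level over the 34 genes, a sum that includes the 3 genes counted elsewhere, while Ins2 had 8 counts with Fusobacterium and 9 with Neisseria against 5701 and Pnlip 0 against 218.

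Of 1383 tested genes under 1 TPM in untreated organoids, 580 rose at least 2-fold with Fusobacterium, 50 with Helicobacter and 199 with Neisseria, while 68, 16 and 65 fell as far, and the filter on low counts favours such risers. Of all 13670 genes below 0.5 TPM in untreated organoids, 218, 19 and 57 reached 1 TPM. Genomic DNA is argued against by olfactory receptor genes, at 7.28 ± 1.13 CPM with Fusobacterium and 6.69 ± 0.469 in untreated organoids (ratio 1.09), and GC bias by abundant genes matched on GC content, whose median change was -0.0366 where the risers had 2.13. Inhibition of histone deacetylases by products of Fusobacterium stays possible, but neither such products nor deacetylase activity was measured. Of 18 measured targets of such inhibitors, a list made after the data were seen, 13 rose and 1 fell. Its camera p was 0.000491 with an estimated correlation and without adjustment, and 8 of the targets are in other lists. The median of the targets was 0.494 with Fusobacterium, 0.0865 with Helicobacter and -0.0531 with Neisseria. With Fusobacterium this lies below the 2.13 of the near-silent risers, so the list does not tell whether such inhibition accounts for them. Neuronal genes did not pass as a list (8 rose and 3 fell of 16 tested genes of 21, camera value 0.186 without adjustment), and H1f0, a linker histone gene chosen after its values were seen, rose from 298 ± 11.3 to 1020 ± 36.6 TPM.

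Lars2 rose by 5.66 ± 0.26 with Fusobacterium and 0.87 ± 0.25 with Neisseria (adjusted p = 0.0193, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Neisseria libraries differed widely, at 30.6 ± 13.6 TPM against 19.2 ± 0.407 in untreated organoids. A shared rise of mitochondrial aminoacyl-tRNA synthetases is argued against, since 13 of the 16 others fell, none rose and their median was -0.348. Whether reads of ribosomal RNA assigned to Lars2 account for the rise cannot be decided here. Its 3' UTR holds AGTACGAGAGGA, 12 bases of large-subunit ribosomal RNA, in exon 21 (chromosome 9, 123462169 to 123462180, GRCm38). Of 21901 genes with protein-coding transcripts, 5 hold these bases, and so short a match can also occur by chance. Only these 12 bases were searched for, so the full length of any match between Lars2 and ribosomal RNA was not measured. The other tested holders, Inpp5b and Neo1, had log2 fold changes of 0.26 and 0.10. Their values do not decide the question, since the lengths of their matches were not measured either. No counts per position were used here. Total RNA was extracted, per the labels, which does not settle whether ribosomal RNA entered the libraries. A biological rise of Lars2 itself was not tested.

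For each comparison of 3 libraries with 3, the real split is 1 of 10, which are too few for a share under 0.05. The real counts were 8356 for Fusobacterium, 2419 for Helicobacter and 6511 for Neisseria against untreated, 8361 for Fusobacterium against Helicobacter, 8527 for Fusobacterium against Neisseria and 4704 for Helicobacter against Neisseria. The highest other split gave 0 calls in edgeR's test in each, with at most 173, 2335, 656, 623, 249 and 1590 genes at an unadjusted p under 0.05. For the 4 groups, 1 of 100 splits, the real one, gave as many as 10352 genes, which is the smallest share that 100 splits can give. The highest other gave 9177, so wrong splits can also give many calls. Each group holds a run of consecutive library numbers, so splits cannot separate the bacterium from the order of the libraries.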
